A study of Rattus norvegicus with 9 samples.

How the data were processed

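Gene expression was measured in the cortex of 9 irradiated Sprague-Dawley rats, 4 males and 5 females, with 1 array per animal. Per the labels' protocols, pregnant dams were irradiated on gestation day 17, the cortex was separated from the hippocampus, RNA was extracted with TRIzol and a column kit with DNase, and 250 ng of it was turned into biotin-labelled cRNA for an Illumina bead array. Each array's deposited file gives 1 intensity per probe on a linear scale for 22517 probes, with no detection p-value, bead count or control probe, and per the values it was not normalised between arrays. The scanner software and its background step are not given in the sources used here. The series' value table holds log2 values that the authors had processed, for 15912 of these probes. Each of its columns kept the rank order of its array's own file (rank correlation 1), rose with the log2 of that file at slopes of 0.974 to 1.04, and had the same maximum of 13.5 and a median of 6.13, which marks quantile normalisation. The values are log2 and not centred per gene, and the distribution they were normalised to stays unknown, since it is not that of these 9 arrays alone. All of its columns belonged to the samples described, and 0 were left unmapped.

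The intensities were corrected for background with limma's normexp method at an offset of 16, quantile normalised and put on a log2 scale. The plan made before the data were examined relied on detection p-values. In their place, background was set from the 6605 probes that the authors left out of the value table. The 99th percentile of their intensity on an array, between 46.6 and 54.1, served as the background bound of that array, and probes above it on at least 4 of the 9 arrays were tested. This kept 12370 probes, of which 8780 had a gene name, for 8577 genes, 3590 had none and 18 belonged to the left-out probes. In these, 9995 exceeded the bound on all arrays. Where no animal of a sex exceeded the bound, the fold is given as at least the other sex's mean over the mean, per array, of the higher of the probe's own value and the lowest value of a probe above the bound.

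Gene names came from the platform's annotation, which gave 1 symbol to 10687 probes and several to 0, and left 5225 probes of the value table unnamed here, besides the 6605 outside it. Of the named probes, 10662 matched a gene in the RefSeq table of assembly GRCr8 by gene identifier, 25 did not, and 0 symbols changed. No genome was used and no coordinates are given. Of the tested genes, 191 had more than 1 probe, and the probe with the highest mean over all arrays stood for the gene in the lists. Values of 291 probes repeated those of another probe on all 9 arrays, 209 of them tested.

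Before the data were examined, the groups, tests, covariates, alternatives, 25 gene lists, 8 correlations and the rule for named genes were fixed, apart from those said to be chosen later. Named genes were, first, called genes, then up to 6 per direction with the smallest p between the sexes where fewer than 20 were called. To these were added the X-linked and Y-linked list members, the 2 members of every other list with the smallest p, and the 12 genes above the bound on all arrays with the largest SD within sex. Males and females were compared with limma's moderated test (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all tested probes, and the title numbers with limma's moderated F test with sex as a covariate. Lists with at least 3 measured members were compared with camera at a preset correlation of 0.01, and again with an estimated correlation, with fry, and by exact permutation of list scores. The lists are not independent of each other, since a few genes stand on 2 lists (Olig2, for example). A list score is the mean over members of the log2 value minus the probe's mean over the animals. List scores between title numbers and correlations of list scores were tested by exact permutation, over all 362880 pairings for a correlation. The labels do not say what the title number marks, and if it marks a litter the animals within it are not independent. Replicate numbers follow the order of the samples and only name the animals.

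The alternatives were no background correction, median scaling, the authors' log2 values, a filter on all 9 arrays, no filter, each animal left out in turn, the title number as a fixed or random block, limma's eBayes with trend and robust settings, and array weights. Chosen after seeing the data were an offset of 50, the left-out probes as negative controls, the authors' probe list as the filter, repeated probes counted once, the 95th percentile as the bound, the first principal component as a covariate, exact permutation of list scores between the sexes, correlations of scores after removal of sex or title number means with pairings permuted within the sexes or numbers, and leaving out the 3 arrays apart on that component. A block by slide was not run because the files used give no slide.

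The code was tested on simulated arrays with the means and spread of the 12370 probes tested, in 10 simulations with 200 probes changed. Between 4 males and 5 females, 44.2% of changes of log2 0.5, 94.5% of log2 1 and 99.9% of log2 2 were recovered, and for a change in the second title number these shares were 0%, 87.2% and 99.3%. On average, 4.8, 10.3 and 10.6 unchanged probes were called between the sexes. The simulated probes varied independently of each other, with 200 of them changed. These shares therefore do not give the chance of finding a change on the real arrays. A shift of 0.3 in the myelin list was called by camera in 10 of 10 simulations. The simulated members were independent, while the measured ones had an estimated correlation of 0.734. That simulation tests the code alone and not how far camera's calls hold on these arrays. The work used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.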

Results

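The cerebral cortex of 9 Sprague-Dawley rats, an outbred laboratory strain, was profiled on Illumina bead arrays, which read a labelled copy of a sample's RNA through gene probes carried on beads. All 9 animals had been exposed to 145 cGy of radiation from a caesium source in the womb, on gestation day 17, and their brains were taken at 60 days of age. The series presents them as a model of cortical dysplasia, a malformation in which the cortex is laid down abnormally. The labels divide the animals into 4 males and 5 females. Each title also carries 1 of 3 running numbers that the labels do not explain. Male 1, female 1 and male 2 share the first title number, male 3, male 4, female 2 and female 3 the second, and female 4 and female 5 the third. Unirradiated animals were part of the design and were not analysed here, so no value reported for these animals measures an effect of radiation. Median raw intensity ranged from 47.9 in male 4 to 57.3 in female 1, and between 11857 probes in male 4 and 12392 in female 1, of 22517 on the array, exceeded the background bound. Log2 intensities of pairs of arrays correlated at 0.979 to 0.993 over the probes tested. The first principal component held 33.5% of the variance and set female 1, male 2 and female 3, at scores of 19.0, 16.1 and 17.5, apart from the other 6 arrays, which lay between -13.1 and -4.53. These 3 arrays came from both sexes and from the first and the second title number. The number of arrays limits the precision of every comparison.

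The arrays measured the main cell types of the cortex in every animal. All 14 genes of glutamatergic neurons and cortical layers and all 12 astrocyte genes that had a named probe exceeded the bound on all 9 arrays. So did 17 of 18 genes of GABAergic interneurons, which make the inhibitory transmitter GABA, and 15 of 16 genes of oligodendrocytes and myelin, the insulating sheath of axons. Among receptor and channel genes, 21 of 25 subunits of GABA and glutamate receptors and 17 of 24 voltage-gated ion channel genes were above the bound throughout. The housekeeping lists stood at 58 of 62 ribosomal protein genes, 24 of 25 genes of oxidative phosphorylation and 10 of 11 genes of protein folding. For neighbouring tissues, the counts were 12 of 12 for striatum and 3 of 13 for choroid plexus, the tissue that secretes cerebrospinal fluid. They were 9 of 13 for meninges, 3 of 8 for hippocampus and 3 of 13 for thalamus and hypothalamus. For vascular and immune cells they were 6 of 9 endothelial, 5 of 8 blood cell and 10 of 14 microglial genes, and 13 of 22 genes of antigen presentation and interferon response. Of the signalling lists, 14 of 16 immediate early genes, which neurons switch on within minutes of firing, were above the bound on all arrays, beside 10 of 15 glucocorticoid-responsive genes, 5 of 9 genes of sex steroid and growth hormone signalling, 3 of 5 of oligodendrocyte precursors and 3 of 3 X-linked genes. Of 15 p53 target and DNA damage genes with a named probe, 9 were above the bound on all arrays. Cdkn1a, which halts the cell cycle, Bax and Pmaip1, which promote cell death, and Tp53inp1, Polk and Chek2 were not. Over the 25 lists, 382 entries had a named probe, of which 296 exceeded the bound on all 9 arrays and 7 on none. None of the 12 Y-linked genes listed had a named probe, so the sex on the labels could not be checked through them.

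Between irradiated males and females, the sexes being the only groups the labels give, no gene passed the test over all probes. Cmc1 (probe ILMN_1355117), a factor for the assembly of cytochrome c oxidase in mitochondria, read 7.81 ± 0.26 on the log2 scale in males (SD, n = 4) and 7.08 ± 0.08 in females (SD, n = 5). The difference was 0.73 ± 0.12 (SE), with an adjusted p of 0.207. Bcat1 (ILMN_2040300), which transfers amino groups from branched-chain amino acids, read 7.82 ± 0.42 in males and 6.87 ± 0.18 in females. It was 0.95 ± 0.17 higher in males (SE), with an adjusted p of 0.434. Uggt1 (ILMN_1364029), a sensor of misfolded glycoproteins in the endoplasmic reticulum, was above the bound in 5 of 5 females and in 0 of 4 males. Its means were 5.32 and 4.85, which makes the female level at least 1.20-fold higher (adjusted p 0.655). Eif2s3 (ILMN_1650549), the X-linked subunit of a factor that starts translation, stood at 5.82 ± 0.11 in males and 6.25 ± 0.23 in females. It was the only gene called when adjusted over the list alone, at an adjusted p of 0.010 among 3 X-linked genes. The other X-linked genes, the RNA helicase Ddx3x and the deubiquitinase Usp9x, differed by -0.14 ± 0.10 and -0.13 ± 0.11 (male minus female, SE).

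Further genes with small p were higher in males by 0.36 ± 0.08 for Cradd, an adaptor of cell death signalling, by 0.39 ± 0.10 for the endosomal GTPase Rab7b and by 0.43 ± 0.12 for the secreted matrix protease Mmp9. Upk1a, a membrane protein known from the urinary tract, differed by 0.34 ± 0.09 and exceeded the bound in 4 of 4 males and 1 of 5 females. Lower in males were Abcg2, an efflux transporter of brain capillaries, at -0.53 ± 0.13, the RNA helicase Ddx31 at -0.35 ± 0.09, the telomerase cofactor Wrap53 at -0.30 ± 0.09 and Pid1, an adaptor tied to insulin signalling, at -0.30 ± 0.09. Within the first and the second title number, which hold both sexes, Cmc1 was higher in males by 0.78 and 0.67, Bcat1 by 0.67 and 1.22, and Eif2s3 differed by -0.33 and -0.60. In limma, 0 of 12370 probes passed an adjusted p of 0.05. An unadjusted p under 0.05 was found for 239, where evenly spread p-values give 618.5. Of these, 95 were higher in males and 144 in females. Below the unadjusted 0.001 that the series' design text names stood 5 probes, where evenly spread p-values give 12.4. Of them, 3 were higher in males (Cmc1, Bcat1 and Cradd) and 2 higher in females (Uggt1 and the unnamed ILMN_1354896). Without female 3 there were 8 probes below 0.001. Other splits of the animals into 4 and 5, tested the same way, gave a median of 407 probes under 0.05 and 5 under 0.001. The counts of 239 and 5 thus cannot be read as below chance. The unnamed probe was singled out after its values were seen. It was above the bound in 5 of 5 females and 1 of 4 males and differed by -0.97 ± 0.14 (adjusted p 0.207). Leaving out male 1 called 2 probes, Bcat1 at 1.14 with an adjusted p of 0.0273 and ILMN_1354896 with 0.0278, which was then above the bound in 0 of 3 males and at least 1.78-fold higher in females. Leaving out male 4 called 1, Cmc1 at 0.85 with 0.0193.

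**Figure D1:**
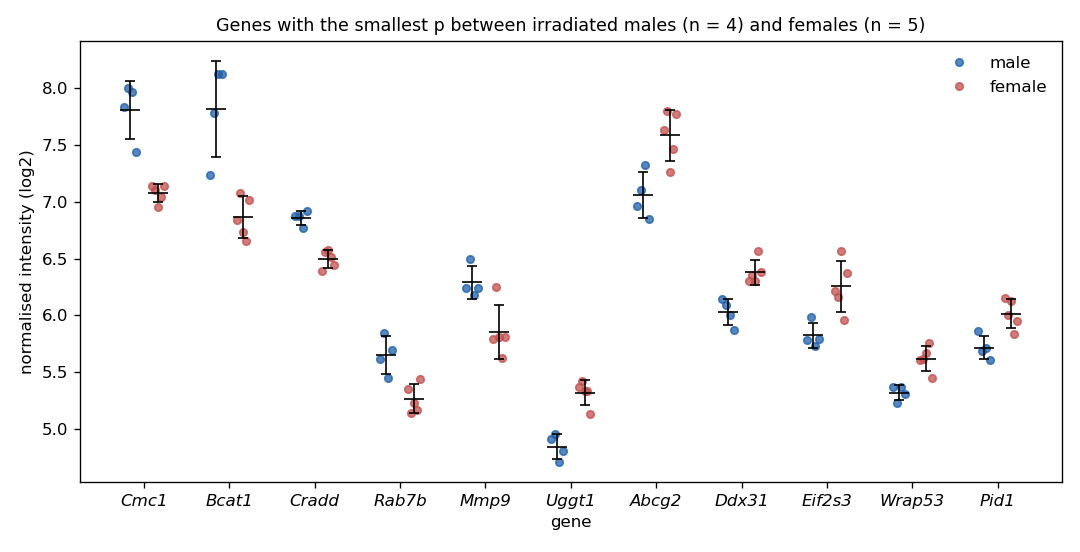
Normalised log2 intensity of named genes with the smallest p between the sexes in 4 irradiated males (blue) and 5 irradiated females (red), with 1 point per animal and bars at the mean and SD. Cmc1 is at least 7.44 in every male and at most 7.14 in every female, and none of the genes passed the test over all probes.

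Among gene lists fixed in advance, 6 were shifted toward females. Genes of the striatum, the structure under the cortex that receives its output, were higher in females for 11 of 12 members, at a median of -0.25 (male minus female). Among them were the cyclic nucleotide phosphodiesterase Pde10a at -0.39 ± 0.18 (SE) and the adenylate cyclase Adcy5 at -0.24 ± 0.11. Of the choroid plexus list, 6 of 7 members were higher in females at a median of -0.32, or -0.08 without female 1. The BMP antagonist Sostdc1, above the bound in 3 of 5 females and 1 of 4 males, differed by -0.94 ± 0.51, or by -0.40 without female 1. The water channel Aqp1 was above the bound in 4 of 5 females and 0 of 4 males, at least 1.12-fold higher in females. Of 12 glucocorticoid-responsive genes, 11 were higher in females at a median of -0.18, with Pdk4, which restrains glucose oxidation, at -0.33 ± 0.17 and the transcription factor Zbtb16 at -0.23 ± 0.15. The same direction was found for 18 of 22 voltage-gated channels, with the sodium channel subunits Scn3b and Scn2a at -0.16 ± 0.11 and -0.17 ± 0.12. It was also found for 13 of 15 immediate early genes, with the transcription factors Egr1 and Egr2 at -0.25 ± 0.17 and -0.34 ± 0.30. All 3 X-linked genes were higher in females, at a median of -0.14. In camera with a preset correlation of 0.01, adjusted p was 0.000116 for striatum, 0.00153 for the X-linked list, 0.00678 for glucocorticoid-responsive genes, 0.00719 for choroid plexus, 0.0228 for channels and 0.0487 for immediate early genes. None of these calls held, at an adjusted p = 0.482 with an estimated correlation for striatum, choroid plexus and glucocorticoid-responsive genes, 0.336 for the X-linked list, 0.458 for channels and 0.626 for immediate early genes. The choroid plexus score, the mean log2 deviation of the list's members from their mean over all animals, was 1.44 in female 1 and from -0.51 to 0.46 in the others.

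The remaining 4 called lists were shifted toward males. Myelin and oligodendrocyte genes were higher in males for 15 of 16 members at a median of 0.19, with Aspa, which breaks down N-acetylaspartate, at 0.22 ± 0.13, while the lineage factor Olig2 went the other way at -0.17 ± 0.09. Genes of blood cells were higher for 6 of 7 members at a median of 0.13, with the haemoglobin chains Hbb-b1 and Hbb at 0.39 ± 0.20 and 0.40 ± 0.24. Genes of meninges and fibroblasts were higher for 11 of 13 at a median of 0.18, with the collagen chain Col1a1 and the retinoic acid enzyme Aldh1a2 at 0.22 ± 0.17 and 0.22 ± 0.18. In the list of antigen presentation and interferon response, 14 of 20 were higher at a median of 0.04, with the interferon-induced GTPases Mx1 and Mx2 at 0.27 ± 0.10 and 0.34 ± 0.15. Of the list genes named, Olig2, Pdk4 and Star exceeded the bound in 3 of 4 males, Zbtb16 in 2 of 4 males, Aldh1a2 and Prox1 in 4 of 5 females, and Col1a1 and Flt1 in 3 of 4 males and 3 of 5 females. Adjusted p in camera was 0.0228 for myelin and for blood cells, 0.0311 for meninges and 0.0414 for antigen presentation. These calls were lost too, at an adjusted p = 0.626 with an estimated correlation for myelin and meninges, 0.482 for blood cells and 0.520 for antigen presentation. In all, 10 of 24 lists with at least 3 measured members were called, and no member of any list was called over all probes.

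With the title number in the fit as a block, 6 lists were called. Striatum (0.000219), immediate early genes (0.000442), choroid plexus (0.00548), glucocorticoid-responsive genes (0.0295) and channels (0.0295) kept an adjusted p under 0.05, and ribosomal proteins passed at 3.5e-05 toward males. None of these 6 calls held, at an adjusted p = 0.753 with an estimated correlation for striatum, immediate early genes, choroid plexus and glucocorticoid-responsive genes and 0.536 for channels and ribosomal proteins. The X-linked list (0.0534), blood cells (0.0556), antigen presentation (0.348) and meninges (0.816) did not pass, and myelin turned toward females at 0.816. Within the first and the second title number, male minus female list scores were -0.21 and -0.24 for X-linked genes, -0.72 and -0.13 for striatum, -0.22 and -0.44 for immediate early genes, -0.16 and -0.05 for channels and 0.12 and 0.24 for blood cells. The sign differed between the numbers for choroid plexus (-1.81 and 0.13), glucocorticoid-responsive genes (0.04 and -0.38), myelin (0.05 and -0.07), meninges (-0.42 and 0.31) and antigen presentation (-0.07 and 0.14). Leaving out the 3 arrays that stood apart, chosen after seeing the data, left 4 lists called, at adjusted p of 0.0401 for X-linked genes, 0.00483 for antigen presentation, 0.0417 for blood cells and 2.17e-09 for meninges. These 4 were lost at an adjusted p = 0.529 with an estimated correlation for X-linked genes, antigen presentation and meninges and 0.542 for blood cells. Leaving out these arrays ended the calls for striatum (0.691), myelin (0.272), choroid plexus (0.121), channels (0.0879), glucocorticoid-responsive genes (0.0879) and immediate early genes (0.0688). In an exact permutation test of the list scores, two-sided, the X-linked list had the smallest p at 0.0159, adjusted to 0.381. Its scores lay from -0.18 to -0.09 in the 4 males and from -0.05 to 0.29 in the 5 females.

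Single animals decided most list calls, and at the preset correlation the X-linked and striatal calls alone stayed when any 1 array was left out. Whichever animal was left out, neither was called with an estimated correlation, at an adjusted p from 0.217 to 0.619 for the X-linked list and from 0.322 to 0.675 for striatum. The choroid plexus call ended without female 1 (adjusted p 0.113). The glucocorticoid call ended without male 3 (0.657) or female 3 (0.0637), and the channel call without female 1 (0.200), male 3 (0.130) or female 5 (0.0761). The call for immediate early genes ended without male 1 (0.430), female 1 (0.250), female 2 (0.231), female 3 (0.318) or female 4 (0.0580), and turned toward males without male 3 (0.648). Myelin ended without male 2 (0.264), male 3 (0.291) or female 3 (0.0637) and turned without female 4 (0.593), whose myelin score was -0.84. Blood cells ended without male 4 (0.322), female 3 (0.0593) or female 5 (0.218). Meninges ended without male 1 (0.0573), male 3 (0.172), male 4 (0.440) or female 2 (0.238) and turned without female 5 (0.845), whose score was -0.77. Antigen presentation ended without male 3 (0.376), male 4 (0.245), female 2 (0.136) or female 5 (0.576). List medians moved with them. For immediate early genes, at -0.14 over all animals, the median was -0.05 without male 1, -0.38 without male 2, 0.05 without male 3, -0.27 without male 4, -0.23 without female 4 and -0.25 without female 5. For channels, at -0.08, it was -0.04 without female 1 and -0.05 without male 3. The glucocorticoid median was -0.04 without male 3, -0.28 without male 4 and -0.27 without female 5, and the X-linked median -0.09 without female 5. For myelin it was 0.28 without male 4, 0.33 without female 2 and -0.01 without female 4, for blood cells 0.07 without female 5. The meninges median was 0.03 without male 4, 0.11 without female 2 and 0.01 without female 5, where the test pointed toward females. The antigen presentation median was 0.08 without male 1, 0.06 without male 2, 0.10 without female 3, 0.11 without female 4 and -0.01 without female 5, where the test pointed toward males.

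The differences of single genes moved with the animals too. Without 1 animal, 35 of 59 named genes moved by over 1.5 times and 0 turned. Among members of the called lists, leaving out female 1 gave -0.25 for Pde10a and -0.11 for Scn2a, which stood at -0.26 without female 3. Leaving out male 4 gave -0.16 for Adcy5, -0.11 for Scn3b, 0.24 for Hbb-b1, 0.21 for Hbb, 0.14 for Col1a1, -0.57 for Egr2 and -0.35 for Zbtb16. Leaving out male 2 gave 0.17 for Mx2, 0.59 for Hbb-b1, 0.36 for Col1a1 and 0.38 for Aldh1a2. Without male 1, Egr1 and Egr2 stood at -0.17 each and Zbtb16 at -0.14. Without male 3, Egr1 stood at -0.11, Egr2 at -0.12, Zbtb16 at -0.13 and Pdk4 at -0.17, and Pdk4 was at -0.20 without female 2. Without female 4, Aspa stood at 0.10. Without female 5, the values were -0.55 for Egr2, 0.10 for Col1a1, 0.08 for Aldh1a2, -0.08 for Ddx3x and -0.09 for Usp9x.

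Other processing ended list calls too. With a filter on all 9 arrays the calls for choroid plexus (0.447), meninges (0.147), antigen presentation (0.0919) and immediate early genes (0.0722) ended. Without a filter those for antigen presentation (0.0809) and blood cells (0.0753) ended. The call for immediate early genes also ended without background correction (0.0588) and with the authors' values (0.0578). Of the alternatives chosen after seeing the data, an offset of 50 ended the calls for antigen presentation (0.0601), meninges (0.0535) and immediate early genes (0.0738). The authors' probe list ended those for antigen presentation (0.0751), blood cells (0.0654) and immediate early genes (0.0543). The first principal component as a covariate ended those for antigen presentation and blood cells (0.0631 each), meninges (0.0613) and immediate early genes (0.124).

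The other 14 lists did not pass this test between the sexes, at adjusted p from 0.0522 to 0.784. Among neuronal genes, the deep-layer factor Fezf2 differed by 0.25 ± 0.12 (male minus female, SE), and the kinase Camk2a by -0.33 ± 0.18. The neuropeptide Sst differed by 0.20 ± 0.11, the interneuron factor Dlx5 by -0.30 ± 0.17, and the receptor subunits Grik2 and Gabbr1 by -0.26 ± 0.11 and -0.29 ± 0.14. The glutamatergic list had a median of -0.01 and a mean of 0.01, and its test pointed toward males. Of glial and vascular genes, the lysosomal protease Ctss of microglia differed by -0.29 ± 0.11 and Laptm5 by -0.15 ± 0.09, and the astrocyte genes Fgfr3 and Mlc1 by -0.17 ± 0.11 and -0.13 ± 0.10. The precursor proteoglycan Bcan differed by -0.12 ± 0.08, and the endothelial receptors Tie1 and Flt1 by 0.16 ± 0.09 and 0.10 ± 0.12, with 0.04 at a second probe of Tie1. The neuropeptide Trh was above the bound in 5 of 5 females and 1 of 4 males and differed by -0.78 ± 0.26. Pomc differed by 0.27 ± 0.13, and the hippocampal genes Prox1 and C1ql2 by 0.10 ± 0.10 and -0.12 ± 0.14. Stress and hormone genes gave -0.21 ± 0.10 for Sesn1 and 0.12 ± 0.08 for Plk2, both p53 targets, and -0.12 ± 0.09 for Star, which brings cholesterol into mitochondria. They gave 0.13 ± 0.14 for the progesterone receptor Pgr, and 0.26 ± 0.25 and -0.13 ± 0.15 for the chaperones Hspe1 and Hspa5. The respiratory chain genes Ndufa5 and Uqcrc1 differed by 0.23 ± 0.15 and -0.12 ± 0.09, and Rpl6 and Rpl17 by -0.27 ± 0.10 and 0.20 ± 0.12. Ribosomal proteins (0.0522, or 0.645 with an estimated correlation) passed without male 1 (0.0125), male 2 (0.00391), female 2 (0.0274), female 4 (0.00816) or female 5 (0.0351). So did receptor subunits (0.0722) without male 2 (0.0186) or female 2 (0.0274), oligodendrocyte precursors (0.151) without female 1 (0.0358), and astrocytes (0.197) and microglia (0.227) both without male 3 (0.0289). Ribosomal proteins also passed without background correction (0.0492), with median scaling (0.0105), with the authors' values (0.0495) and with repeated probes counted once (0.0429), and receptor subunits with median scaling (0.0427). None of these calls held either. Without single animals, the adjusted p with an estimated correlation was 0.603 to 0.745 for ribosomal proteins, 0.554 and 0.419 for receptor subunits, 0.468 for precursors, 0.409 for astrocytes and 0.553 for microglia. With other processing, the adjusted p with an estimated correlation was 0.629 to 0.788 for ribosomal proteins and 0.671 for receptor subunits.

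Between the numbers in the titles, no gene passed the test, with sex kept in the fit. The genes with the smallest p, named after their values were seen, were Zfp317, a zinc finger protein, at means of 6.89 ± 0.56, 5.62 ± 0.48 and 6.25 ± 0.39 in the first, the second and the third title number (SD, n = 3, 4 and 2, adjusted p 0.126), and Atp5mk. Atp5mk, a small subunit of ATP synthase, read 6.52 ± 0.22, 7.05 ± 0.29 and 7.42 ± 0.10 (adjusted p 0.126). Among those that followed, Blnk, an adaptor of B cell receptor signalling, read 5.18 ± 0.48, 5.91 ± 0.30 and 5.83 ± 0.09 (adjusted p 0.134), and Rbm3, a cold-induced RNA binding protein, 7.19 ± 0.28, 7.54 ± 0.32 and 7.82 ± 0.10 (adjusted p 0.245). Limma's moderated F test called 0 of 12370 probes. An unadjusted p under 0.05 was found for 1141, where evenly spread p-values give 618.5, and one under 0.001 for 30, where they give 12.4. Such counts vary widely on these arrays. Other splits of the animals into 4 and 5, tested as the sexes were, gave a median of 407 and up to 2887 probes under 0.05. Under 0.001 they gave up to 239. Title numbers were not permuted over genes, so 1141 and 30 cannot be read as above chance. The count of 30 became 3 without female 1, 17 without male 3, 18 without male 4, 19 without female 4, 48 without female 2 and 57 without female 5. Without a filter on dim probes Zfp317 alone was called (adjusted p 0.0302). Leaving out female 5 called Zfp317 (0.0322), the imprinted membrane protein Nnat (0.0372) and Hap1, a partner of huntingtin (0.00696). Leaving out female 2 called 3 probes, the mitochondrial protein Bnip3 (0.00528), ILMN_1650254 (2.99e-07) and ILMN_1351707 (2.87e-05), and leaving out male 4 called ILMN_1374322 (0.00531). Both ILMN_1650254 and ILMN_1351707 read at separate high and low levels. Male 3, male 4 and female 3 had means of 9.39 and 4.92 for them, and the other animals, female 2 included, 4.83 and 7.45. Leaving out female 2 thus put all of the second title number on the same level. Without the 3 arrays apart, Spock2, a proteoglycan of the brain matrix (0.00504), and ILMN_1650254 (0.0175) were called. That fit left male 1 alone in the first title number and female 2, low in Spock2 at 6.54, as the only female of the second. The third title number held females only, and a lone animal, as in that fit or without female 4 or female 5, was taken to vary like the others.

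Of the gene lists, microglia had the smallest p between the title numbers when scores were permuted over all animals, at mean scores of -0.14 ± 0.06 in the first, 0.06 ± 0.06 in the second and 0.08 ± 0.15 in the third (SD). The exact permutation p was 0.0421, adjusted to 0.709 over 24 lists. Hippocampal genes scored -0.08 ± 0.09, 0.00 ± 0.05 and 0.12 ± 0.13 at an exact p of 0.0849, and genes of sex steroid and growth hormone signalling 0.03 ± 0.06, -0.06 ± 0.06 and 0.06 ± 0.04 at an exact p of 0.0976, both adjusted to 0.709. The third title number held females only. With scores permuted within sex, the channels had the smallest exact p at 0.0444 and microglia had 0.111. No list passed either way, and the smallest adjusted p within sex was 0.778. With 180 arrangements within sex, no single list could pass that test after adjustment over 24 lists.

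Over all 9 animals, the lists of immediate early, choroid plexus and myelin genes had the largest median SD between animals of the same sex and treatment. Over all probes tested, the SD between animals of the same sex had a median of 0.166 and a 95th percentile of 0.346, and 19 probes exceeded 1. The median SD of a list's members reached 0.475 for immediate early genes, 0.470 for choroid plexus, 0.444 for myelin, 0.371 for both striatum and meninges, 0.321 for blood cells and 0.312 for glucocorticoid-responsive genes. The choroid plexus value was 0.285 without female 1 and 0.303 without female 4, that of myelin 0.307 without female 4 and that of blood cells 0.189 without female 5. In all, 15 of 24 lists lay above the 95th percentile of 10000 random lists matched in size and mean expression. Female 4 had a myelin score of -0.84, with myelin basic protein, Mbp, at 8.90 against 10.07 to 10.82 in the other animals. Male 3 scored -0.67 for immediate early genes and -0.49 for glucocorticoid-responsive genes, with Fos at 6.51 against 7.01 to 8.15. Female 5 scored -0.77 for meninges and -0.36 for blood cells, with the collagen chain Col1a2 at 7.33 against 8.29 to 9.77. Mbp, Fos and Col1a2 were picked after their values were seen. By contrast, genes of oxidative phosphorylation had a median SD of 0.138, oligodendrocyte precursors 0.134 and endothelial cells 0.148, below the medians of 0.152, 0.160 and 0.165 of their matched random lists.

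**Figure D2:**
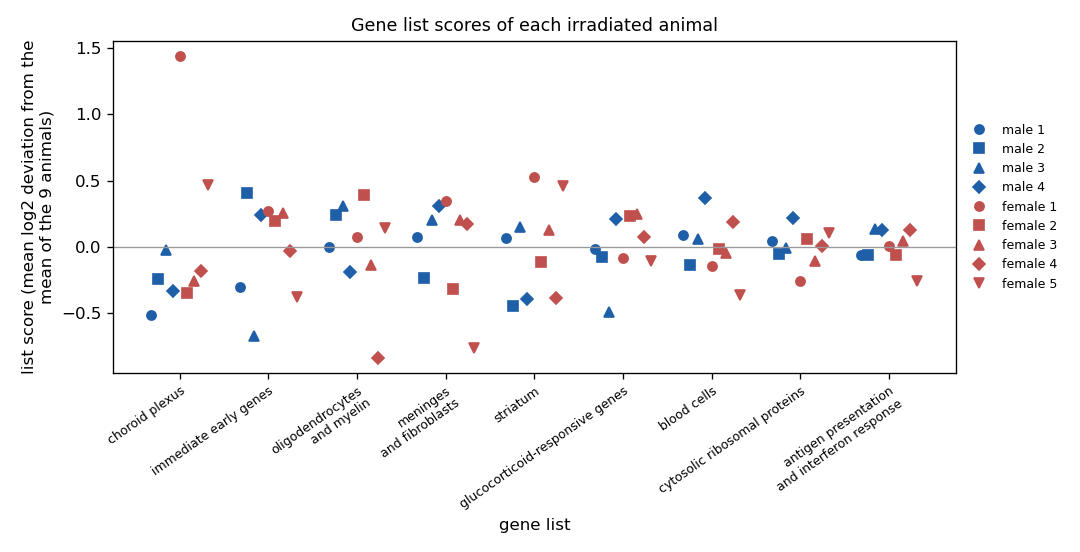
Score of each animal (mean log2 deviation of a list's members from their mean over the 9 animals) for the 9 gene lists whose scores varied most within sex, with males in blue, females in red and 1 symbol per animal. Choroid plexus is highest in female 1 at 1.44, myelin lowest in female 4 at -0.84 and meninges lowest in female 5 at -0.77.

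Among single genes above the bound on all 9 arrays, the largest SD within sex was 2.42 for the ribosomal protein gene Rps9, which read between 5.11 and 5.38 in female 1, male 3, female 3 and female 4 and between 9.50 and 9.88 in the other 5. The ribosomal protein gene Rpl30 (SD 1.99) read 6.31 to 6.78 in male 3, female 2 and female 4 and 9.94 to 10.82 elsewhere. Ttr, the thyroxine carrier made by choroid plexus (SD 2.0), read 12.01 in female 1, 9.49 in female 5 and 5.66 to 7.62 in the rest, and its SD was 1.30 without female 1. Spock2 (SD 1.52) read 6.54 in female 2 and 10.75 to 11.1 elsewhere, with an SD of 0.10 without female 2. The carbonic anhydrase Car3 had an SD of 1.51, the matricellular protein Ccn1 1.17 and the striatal adenosine receptor Adora2a 1.03. Those that followed were the dynein chain Dynlt3 0.88, the phosphatase Dusp1 0.84, the meningeal proteoglycan Ogn 0.81, and the transporter Slco1a5 and the synaptic immediate early gene Arc 0.80 each. Without male 2 the SD of Ccn1 was 0.70, without female 1 that of Slco1a5 was 0.14, and without male 3 that of Arc was 0.52. Without the 3 arrays apart the SD was 0.17 for both Ccn1 and Slco1a5.

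**Figure D3:**
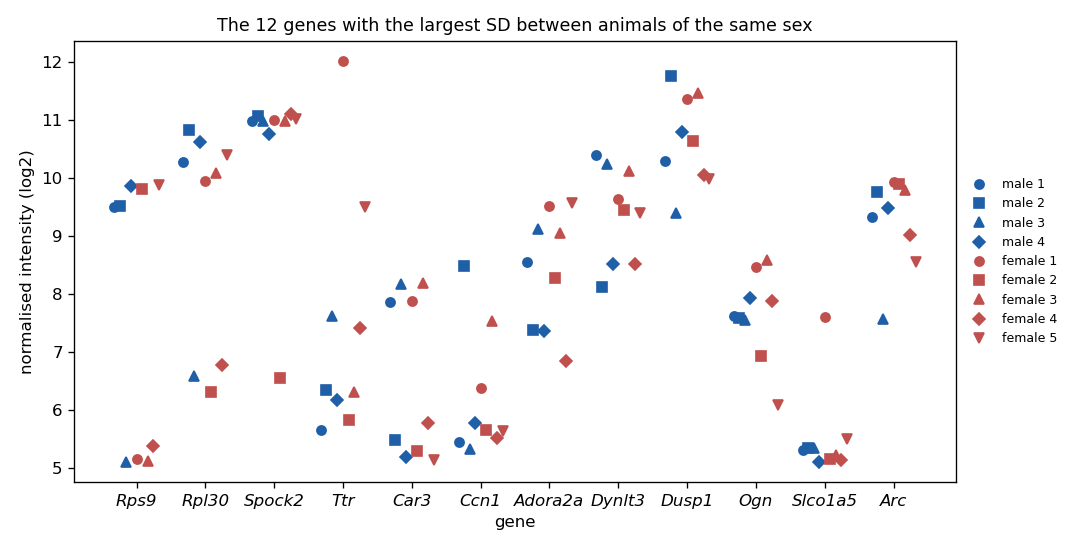
Normalised log2 intensity in each of the 9 irradiated animals of the 12 genes with the largest SD within sex, with males in blue, females in red and 1 symbol per animal. Rps9 and Rpl30 fall on separate high and low levels, Spock2 is low in female 2 alone at 6.54, and Ttr is highest in female 1 at 12.01.

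Of the 8 relations between list scores fixed in advance, none passed the adjusted threshold. Scores of ribosomal protein genes and of oxidative phosphorylation correlated at r = 0.766 (exact permutation p 0.00998, adjusted p 0.0628 over 8 relations, n = 9), with a rho of 0.867 (exact p 0.00451) and r = 0.888 without the 2 animals farthest from the median. Both lists were lowest in female 1, male 2 and female 3, the arrays apart on the first principal component, and within the other 6 arrays r was 0.635. Myelin and glutamatergic scores gave r = 0.812 (exact p 0.0157, adjusted p 0.0628, rho 0.60 with p 0.0968), and r was 0.328 without female 4 and female 2. It was 0.423 without female 4 alone and 0.797 without female 2 alone, so the relation rests on female 4. Immediate early and glucocorticoid-responsive genes gave r = 0.702 (exact p 0.0303, adjusted p 0.0809, rho 0.400 with p 0.291), with r = 0.101 without male 3 and female 5. It was 0.360 without male 3 alone and 0.699 without female 5 alone, so r over all 9 animals depended on male 3. Within the 6 arrays other than those apart on the first principal component, male 3 among them, r was 0.958 and rho 0.943. Those arrays were not tested without male 3. Microglial and antigen presentation genes gave r = 0.624 (exact p 0.0706, adjusted p 0.114, rho 0.800 with p 0.0138) and 0.591 without 2 animals.

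The other 4 relations, of genes that neighbouring tissues or vessels share with the cortex, had exact p of 0.0710 or more. Hippocampal and striatal scores gave r = -0.617 (exact p 0.0710, adjusted p 0.114, rho -0.567 with p 0.121, r = -0.279 without 2 animals), and striatal and glutamatergic scores r = 0.483 (exact p 0.186, adjusted p 0.248, rho 0.200 with p 0.613, r = 0.576 without 2). With median scaling, these r were -0.277 and 0.680. The striatal and glutamatergic r was 0.298 without female 4 and 0.685 without male 2. Endothelial and blood cell scores gave r = 0.314 (exact p 0.411, adjusted p 0.470, rho 0.183 with p 0.644, r = -0.112 without 2), and choroid plexus and meninges r = 0.0418 (exact p 0.932, adjusted p 0.932, rho 0.183 with p 0.644, r = 0.222 without 2). After each sex's mean was removed and values were permuted over all animals, 3 of the 8 relations passed after adjustment, namely myelin with glutamatergic genes (r = 0.826, exact p 0.00941), ribosomal proteins with oxidative phosphorylation (r = 0.793, exact p 0.0130) and hippocampus with striatum (r = -0.755, exact p 0.0161). Permuted within the sexes, which was chosen after seeing the data, none passed, and the adjusted p of these 3 was 0.101. Leaving out 1 animal also made calls. The ribosomal relation passed without female 1 (r = 0.822) or male 2 (0.803), the myelin relation without female 1 (0.864) or male 3 (0.929), the activity relation without male 2 (0.832) and the microglial relation without female 5 (0.873). Groups of animals with the same title number held 3, 4 and 2 animals, too few for a correlation within a single one. After the mean of each title number was removed and values were permuted within the numbers, also chosen after seeing the data, none of the 8 relations passed. The smallest exact p were 0.0174 for microglial with antigen presentation genes (r = 0.919, adjusted p 0.139) and 0.0486 for hippocampus with striatum (r = -0.885, adjusted p 0.185). Ribosomal proteins with oxidative phosphorylation gave r = 0.709 (exact p 0.0694), the activity relation 0.790 (exact p 0.0972), and myelin with glutamatergic genes 0.854 (exact p 0.132). The other 3, striatal with glutamatergic, endothelial with blood cell and choroid plexus with meninges, gave r = 0.570, 0.190 and 0.144 (exact p 0.347, 0.681 and 0.764).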

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

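The tests weighed here were chosen after the result was seen, except the test of choroid plexus genes under the filter, whose prediction came before those genes' values. Values were marked where the highest or lowest animal of a sex lay far from its neighbour relative to the whole range. This marked 16 values in 194 groups, where chance marks about 1 in 20 groups, or 9.7 of them, if genes are chosen without regard to spread. The groups included the genes chosen for the largest SD within sex, and several marked values came from these. That choice favours animals that lie apart, so the count of 16 cannot be read as above chance.

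Among the males, male 3 stood apart with low Pde10a at 8.82, against 8.94 for the next male, and high C1ql2 at 5.73, a synaptic organiser of hippocampal granule cells. Male 2 had the lowest Aldh1a2 at 5.08, Hspe1 at 7.99 and Rpl6 at 11.28, and the highest Ccn1 at 8.48, against 5.77 for the next male, and the highest score of GABA and glutamate receptor subunits at 0.083. Male 1 had the lowest hippocampus score at -0.12 and male 4 the lowest Slco1a5 at 5.10. Among the females, Scn3b was lowest in female 3 at 10.82, Egr2 was lowest in female 5 at 8.52, and Spock2 was lowest in female 2 at 6.54, against 10.97 for the next female. Female 1 had the highest Slco1a5, a transporter of organic anions, at 7.60, against 5.5 for the next female, and the brightest array at a median raw intensity of 57.25, against 50.5 for the next female and 54.3 for male 1, the next of all. In the males, the ribosomal protein genes Rps9 at 5.11 and Rpl30 at 6.58 were lowest in male 3.

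Choroid plexus genes were high in female 1, with Ttr at 12.01, Enpp2 at 11.72, Sostdc1 at 7.89 and the coagulation factor F5 at 6.80. In the other animals Ttr read 5.66 to 9.49, Enpp2 10.14 to 11.24, Sostdc1 4.39 to 5.94 and F5 4.82 to 5.75. Female 5 was the next highest for Ttr, Sostdc1 and F5. The fault of a single probe is argued against, since 5 of the 7 tested choroid plexus genes were highest in female 1. A candidate explanation is choroid plexus tissue in the dissected sample. Of 6 further list genes that lay under the filter, 5 were highest in female 1, among them the transcription factor Otx2 at 6.35 and the hormone coreceptor Kl at 5.76, both above the bound in that animal alone. It stays a hypothesis from 1 animal, in which a biological difference was not tested, and 3 of the 13 named list genes were above the bound on all arrays.

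Some probes read at separate high and low levels, with a gap of at least 60% of a range of at least 1 on the log2 scale. There were 14 such probes, 7 of them named, against a mean of 1.19 and a highest count of 4 in 100 simulations. The simulated values were normal and independent between probes, while several of the measured probes parted the same animals. The simulations therefore do not give the excess over chance. Of the 14, 10 parted the arrays otherwise than the first principal component, among them Rps9, Rpl30, Car3, Egr2, Eprs1 and Washc3, with Rps9 at means of 5.19 and 9.71. An array batch is argued against, since these 10 made 7 distinct splits of the animals, and so is a general loss of ribosomal protein RNA for Rps9 and Rpl30, since the other 57 ribosomal protein genes had a median SD of 0.185 within sex and a highest of 0.672. For Egr2 a sequence variant under the probe is argued against, since its 3 low animals, male 1, male 3 and female 5, were the 3 with the lowest scores of the other 14 immediate early genes, at -0.27, -0.66 and -0.35. For the other 9 probes such a variant, carried by some rats of an outbred strain, may be the source, but 0 of the named genes had a second tested probe, so it cannot be told apart from other causes.

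Female 1, male 2 and female 3 lay apart on the first principal component, which no label explains, and no biological explanation was tested, since they hold both sexes and 2 title numbers. Array brightness is argued against, since 2 of the 3 arrays had a median raw intensity inside the range of 47.9 to 54.3 of the other 6. A neighbouring tissue common to all 3 dissected samples is argued against too, since 0 of the 5 lists for choroid plexus, meninges, hippocampus, striatum, and thalamus and hypothalamus put all 3 on one side of the others. Different tissues in different animals would not do so, and the lists cannot decide about them. RNA handling or labelling may be involved, and 2 of 3 handling lists, ribosomal proteins and oxidative phosphorylation, were lowest in all 3. Chance gives 2.38% per list only for arrays chosen without regard to expression. These 3 were chosen from the same expression values, so the lists decide nothing here. No RNA quality value was at hand either, so RNA handling or labelling cannot be told apart from other causes. Immediate early genes were highest in the same 3, and 3 of 24 lists parted them in all.

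Between the sexes 0 probes were called, a count that every split of the 9 animals into 4 and 5 reaches (100 of 100), so the splits decide nothing about chance there. The highest other split called 207 probes. It set male 1, female 1, male 2 and female 3 against the rest. This side held all 3 arrays apart and also every animal of the first title number. With female 4 in place of male 1, 57 probes were called, and with female 5, 1 probe. With male 3, male 4 or female 2 in that place, 0 were called. The number of called probes thus turned on the animal that joined the 3 arrays. At an unadjusted p under 0.05, however, each of these splits gave 2128 to 2887 probes, against a median of 407 over all splits but the real one. Under 0.001 each gave 73 to 239, against a median of 5. High unadjusted counts thus went with the 3 arrays whichever animal joined them. These arrays were picked by their expression values, and the source of the 207 was not tested. For gene lists, 5 of 100 splits, the real one among them, gave at least the 10 calls of the real one. The highest other gave 11. It set female 1, female 2, female 3 and female 5 against the rest and so differed from the split by sex in female 4 alone. Chance cannot be excluded for the number of called lists.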

How the results depend on the processing

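Leaving out the 3 arrays apart, the first principal component as a covariate, exact permutation of list scores between the sexes, the authors' probe list, the 95th percentile bound, an offset of 50, left-out probes as negative controls, repeated probes counted once and correlations permuted within the sexes or title numbers were chosen after seeing the data. In camera, 10 lists differed between the sexes, and this became 12 with median scaling, 11 with repeated probes counted once, 8 without a filter, 7 with an offset of 50, 7 with the authors' probe list, 6 with a filter on all 9 arrays, 6 with the title number as a block, 6 with the principal component as a covariate, 4 without the 3 arrays apart, 6 to 11 without 1 animal, and 0 with an estimated correlation, with fry (directional or mixed) or by exact permutation. Genes called between the sexes stayed at 0 in every alternative but leaving out 1 animal (0 to 2), with 239 at an unadjusted p under 0.05, and 5 at an unadjusted p under 0.001. The 239 became 679 without a filter, 636 with the number as a block, 460 with the principal component, 458 without the 3 arrays, 391 with the authors' probe list and 156 with a filter on all 9 arrays, and the 5 became 8, 9, 8, 3, 5 and 3 in the same order. For title numbers, 1 gene was called without a filter, 2 without the 3 arrays, 30 at an unadjusted p under 0.001 (51 without a filter, 18 with median scaling, 14 with the principal component, 13 without sex in the fit and 7 without the 3 arrays), and 0 to 3 without 1 animal. Correlations called were 3 after removing sex (0 permuted within the sexes), 0 after removing the title number, 1 each with median scaling, without a filter, with the authors' probe list, with the 95th percentile bound and without the 3 arrays, and 0 to 2 without 1 animal. Directions turned for C1ql2 (0.012 with the number as a block), Hspa5 (0.096 without the 3 arrays), myelin (adjusted p 0.816 with the block, 9.24e-06 to 0.593 without 1 animal), meninges (0.000801 to 0.845), immediate early genes (0.000105 to 0.648), choroid plexus with meninges (r = -0.668 without the 3 arrays, -0.638 to 0.449 without 1 animal) and endothelial with blood cells (-0.0481 to 0.429), and the cause was not tested. Of all other values under the alternatives, 163 of called lists kept direction and call and 53 lost the call, while 292 of lists not called stayed above the threshold and 16 passed it. Lists not called turned direction in 26 of 308 values, over 9 of the 14 lists. Further, 1458 gene differences and 145 correlations kept direction and side of the threshold, 2 and 11 passed it, and 291 gene SDs stayed within 1.5 times their value and 9 did not. The median SD of 0.166 lay between 0.116 and 0.186, and the detection of gene lists went from 296 entries on all arrays to 315 with the 95th percentile. A block by slide was not run. No paired analysis was possible because replicate numbers only name the animals. The title number groups animals of both sexes without pairing them and was run as a block. Signal over background limits genes such as Uggt1 and Aqp1 to bounds.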

Other observations

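The genes named here were chosen after their values were seen, and no test between animals was run on them. RT1-A1 (probe ILMN_1351487), a class I histocompatibility gene, whose products present peptides to T cells, read 5.44 in female 1, 5.45 in male 3 and 5.57 in female 5, between 6.30 and 6.75 in 5 animals, and 7.56 in female 4. RT1-A2 (ILMN_1349776) read 6.03 in male 2, 6.05 in both male 1 and female 3, 6.35 in female 4, 6.51 in male 4, and 7.12 to 7.33 in female 2, female 5, female 1 and male 3. The SD within sex was 0.75 for RT1-A1 and 0.58 for RT1-A2, against a median of 0.166 over all tested probes. The class II gene RT1-Da ran from 5.81 in female 5 to 7.77 in male 3. The SD of the other 4 genes of this family in the list of antigen presentation was 0.67 for RT1-A3, 0.19 for RT1-S3, 0.21 for RT1-Db1 and 0.23 for RT1-Ba.

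The striatal adenosine receptor Adora2a ran from 6.83 in female 4 to 9.57 in female 5, with female 1 at 9.51, and the striatum score was 0.53 in female 1, 0.46 in female 5 and -0.44 in male 2. Car3, a carbonic anhydrase, read 5.13 to 5.77 in male 2, male 4, female 2, female 4 and female 5 and 7.87 to 8.18 in the other 4 animals. Washc3, a part of the complex that shapes endosomes, had a mean of 4.92 over male 3, female 2, female 3 and female 4 and read 7.52 to 7.78 in the other 5.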
